A study of Vitis vinifera with 74 samples.

How the data were processed

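Gene expression was measured in 2 experiments on the grapevine (Vitis vinifera) cultivar Cabernet Franc by sequencing short tags from the 3′ ends of polyadenylated transcripts with the QuantSeq kit on a NextSeq500 instrument, per the labels' protocols. Reads were 85 bp long in the leaf experiment and 75 bp in the bud experiment. The deposited values are raw read counts per gene in 2 tables, with 40 leaf columns and 34 bud columns and the same 42413 gene identifiers in both. The submitters' processing notes name FastQC, STAR and DESeq2, with no version and no role for each; the genome build, the annotation and the counting settings are not given in the sources used here. The deposited counts were whole numbers with a different total in each column. Whether tags shared by near-identical gene copies were counted, and whether the counting used strand, is not stated, so values of genes with close paralogs or antisense partners are uncertain.

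Each column was matched to its sample by the name in the table header and the sample title. In the leaf table the pre-treatment group has 4 header names that occur 2 times each, so those 8 columns were used as members of their group without a sample of their own. All 74 columns were used. The bud samples described here as 72 h carry that time in their titles, while a code in their descriptions reads 75; the title's time is used. None of the 42413 identifiers occurs in the gene table at hand, and the deposited tables hold no gene names or descriptions. Genes are therefore described as groups defined by their response, the gene lists written before the data were examined could not be formed or tested, and few identifiers are printed. The rule for named genes, with the tests, the groups and most alternatives, was written before the data were examined: without gene names at most 2 identifiers that rose and 2 that fell per experiment, taken from genes past the test at any time with at least 5 CPM (counts scaled to a common library size) on average over the experiment and no overlap between ABA and control libraries. Here the 1 with the largest and the 1 with the smallest log2 fold change per experiment are named.

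In leaves, ABA and control were compared at each time with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) in a model with 1 mean for each of the 9 leaf groups. Library sizes were scaled by TMM, genes were kept by filterByExpr with a minimum count of 10, and genes with a Benjamini-Hochberg adjusted p under 0.05 are called changed. This left 13378 genes holding 99.4% of the leaf counts. The same model gave control against pre-treatment and a joint test of whether the ABA effect differed between the 4 times. The labels describe a randomized block layout in quadruplicate, but do not tie a library to a vine, so the p-values measure the spread between these libraries. Description codes place 4 leaf libraries on a second flow cell (control 2 h replicate 1, ABA 24 h replicate 1, and ABA 48 h replicates 3 and 4), and counts of calls without them are given beside the others.

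The plan was to test the bud columns as replicates in the same way. Before that, the columns of each group were compared by a chi-square test over genes with at least 20 counts in the pair. Outside the 48 h controls, bud columns of a group differed by about sampling noise, and the labels state that every library was sequenced in triplicate. The columns of each bud group were therefore added up and counted as 1 sample, which departs from the planned test. A comparison of 2 summed bud libraries has no replicate check and is reported as the number of genes at least 2-fold apart in log2 CPM (TMM scaling, prior count of 2), without a p-value. A further bud test used the 5 ABA and the 5 control libraries with time as a block (edgeR quasi-likelihood), a design chosen after the columns had been compared, as was a linear trend over the 6 control libraries. No time had a second library per treatment. The p-values of the time-block test thus set the ABA effect against its variation between times, and not against a spread between replicate buds of one time. Whether the ABA effect differed between bud times could only be tested with the spread between the 4 control columns of 48 h (3 residual degrees of freedom), which may be technical. Lists made from control buds were planned from called genes, for camera. They were instead made of genes at least 2-fold apart and set against random lists, since each bud group held 1 library. Filtering, by treatment over the summed libraries, left 16214 bud genes holding 99.6% of the counts, of which 12537 were also tested in leaves.

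Leaf and bud effects were compared by the overlap of called genes, with n1 × n2 / N as the overlap of independent lists, by correlation across genes, by the percentile of a list's median among 10000 random lists matched on expression, and by camera and fry (limma 3.58.1) for bud lists in the leaf libraries. The planned Fisher test of the overlaps was not run, since the bud lists of a single time come from no test. Alternatives were DESeq2 1.42.0, DESeq2-type size factors in edgeR (RLE), no count filter, only the compared groups in the fit, the replicate number or the flow cell as a term, and each replicate left out. Added after the data were seen were those on the spread of the 48 h bud columns, on the time-block test, on the control trend and on lists of one tissue in the other. The planned test, with every bud column a replicate, is given as an alternative. Figures were drawn with matplotlib 3.10.9.

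The tests were run on simulated counts drawn from the real means and library sizes. For the bud test with time as a block, changed genes had the same change at all times and no other course over time. The leaf simulation held no shift between flow cells. The real data may depart from these settings, so the rates below may not carry over to them. For the leaf comparison at 24 h, run on 13126 genes, 55% of the 100 genes changed 2-fold and 87% of the 100 changed 4-fold were called, and 9 of 151 calls were false. For 4 h with nothing changed there were 0 calls. For the leaf test of differing effects 49% of 200 changed genes were called, with 1 false call in 99. For the bud test with time as a block, run on 16214 genes, 32% of the 2-fold and 96% of the 4-fold genes were called, with 8 false calls in 136. For the bud control trend 2% of the genes changed 2-fold over 72 h and 22% of those changed 4-fold were called, with 1 false call in 25. Library totals of 1321798 to 2414909 counts in leaves and 1526985 to 2616086 per bud column leave weakly expressed genes with few counts. Limits on undetected genes use 3 counts over the group, and these limits and the 95% intervals cover counting error only.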

Results

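Abscisic acid (ABA), a plant hormone of drought, dormancy and cold responses, was applied to the grapevine cultivar Cabernet Franc in 2 experiments, and transcript levels were followed over hours. The series title places one in cold acclimation and the other in deacclimation. In the acclimation experiment the leaves of potted greenhouse vines were sprayed at noon with 500 mg per litre (1.9 mM) of S-ABA in water with a surfactant, or with water and surfactant alone. Leaves were sampled before treatment (8 libraries) and at 2, 4, 24 and 48 h in control and ABA vines (4 libraries per group). In the deacclimation experiment single-node cuttings of field-grown vines, with buds at the woolly stage, were sprayed with 1322 mg per litre (5 mM) of S-ABA or with water. Buds were represented by 3 count columns before treatment and by 3 columns for control and ABA at 6, 12, 24, 48 and 72 h, with 4 columns for the 48 h control. Total counts ran from 1321798 to 2414909 per leaf library (median 2084499) and from 1526985 to 2616086 per bud column. Testing covered 13378 genes in leaves and 16214 in buds. The dose, the times, the tissue and the year of the experiments differ, so leaf and bud values are set side by side and not tested against each other.

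The columns of a group were compared first, because the labels state that each library was sequenced in triplicate. Over genes with at least 20 counts in a pair, leaf libraries of a group differed with a chi-square per degree of freedom of 3.85 to 25.4 (median 8.15, 76 pairs), where 1 is sampling noise. The 66 leaf pairs from one flow cell gave 3.85 to 18.5, and the 10 pairs across flow cells 13.1 to 25.4. In 10 of the 11 bud groups the 30 pairs gave 1.02 to 1.17 (median 1.08). These bud columns differed by about the sampling noise and were counted as 1 sample per group, by adding them up. The 4 control columns of 48 h differed more, at 1.34 to 2.00, and were summed in the same way. The summed bud libraries held 4923240 to 7698363 counts.

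**Figure D1:**
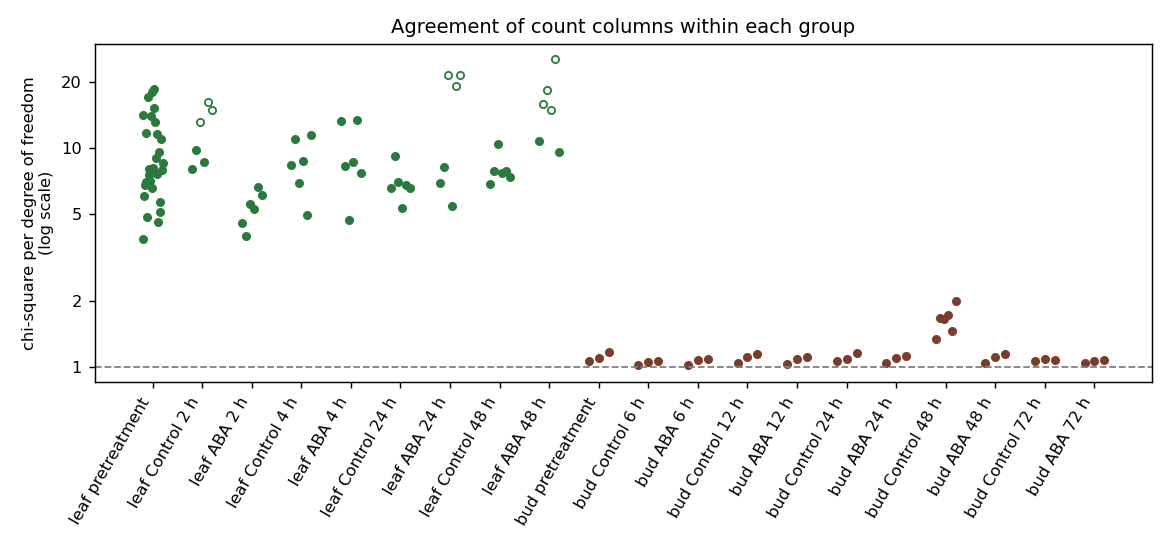
Chi-square per degree of freedom (log scale) of each pair of count columns within a group, with the dashed line at sampling noise (1); open circles are pairs across flow cells. Bud pairs outside the 48 h control lie between 1.02 and 1.17, and leaf pairs lie at 3.85 or above.

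ABA changed few leaf genes at 2 h and many more from 4 h onward. At 2 h 12 genes rose and 1 fell, at 4 h 118 rose and 90 fell, at 24 h 264 rose and 158 fell, and at 48 h 209 rose and 87 fell (edgeR, adjusted p under 0.05). At least 2-fold higher were 10, 83, 170 and 149 of them, and at least 2-fold lower 1, 52, 67 and 35, in order of time. The median log2 change of the genes that rose was 1.93 at 2 h, 1.36 at 4 h, 1.26 at 24 h and 1.47 at 48 h. The median of those that fell was −1.67, −1.19, −0.92 and −0.93. Without the 4 libraries of the second flow cell the counts were 10, 342, 412 and 164, and with only the compared groups in the fit 262 at 24 h and 56 at 48 h. DESeq2 called 33 genes at 2 h and 338 at 4 h, and leaving out the count filter gave 27 at 2 h. The balance at 4 h depended on the samples and the method, with 61 up and 73 down without control replicate 1, 82 and 92 without control replicate 4, and 169 and 169 by DESeq2.

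Single libraries moved these counts. At 2 h leaving out an ABA library gave 4 (replicate 1), 5 (replicate 2) or 20 (replicate 4) calls, and leaving out a control library 5 (replicate 1), 6 (replicate 2) or 6 (replicate 3). At 4 h the count was 134, 109 and 68 without control replicates 1, 2 and 3, and 80, 101 and 120 without ABA replicates 1, 3 and 4. At 24 h it was 234 and 278 without control replicates 2 and 4. At 48 h it was 160 and 123 without control replicates 1 and 4, 640 without ABA replicate 1 and 127 without ABA replicate 3.

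The leaf gene with the largest rise by the naming rule, Vitvi05g00204, had no count in the 4 control libraries of 48 h and 536 counts in the 4 ABA libraries. Its level was at least 168-fold higher with ABA, with 3 counts over the control group as the floor (edgeR adjusted p = 0.00457). Of these counts 470 came from ABA replicate 2, and without it the bound was 27.3-fold. It reached 65.2 ± 111 CPM (SD, n = 4) at 48 h, with 3.50, 232, 4.52 and 21.0 CPM in replicates 1 to 4. At 24 h Vitvi05g00204 stood at 69.5 ± 87.5 CPM (SD, n = 4) with ABA and at 1 count in all in the controls (edgeR adjusted p = 0.00294). The leaf gene with the largest fall by the naming rule, Vitvi08g00768, was at 14.1 ± 4.71 CPM (SD, n = 4) in controls and 0.507 ± 0.724 CPM with ABA at 24 h, with every ABA library below every control library. Its log2 change was −4.84 ± 0.80 (SE) at 24 h (edgeR adjusted p = 0.000366), −3.16 at 4 h (0.00542) and −3.11 at 48 h (0.0144). At 2 h Vitvi08g00768 had a log2 change of −2.39 that did not pass (0.105).

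Genes that rose at one time from 4 h onward were often called at the next. Of the genes higher at 24 and at 48 h, 92 were shared, against 4.12 for independent lists, and of the lower ones 30 against 1.03. The 4 and 24 h lists shared 50 higher genes (2.33) and 12 lower genes (1.06), and the 4 and 48 h lists 43 (1.84) and 4 (0.585). Of the 12 genes higher at 2 h, 10 were also called higher at 4 h (0.106), 9 at 24 h (0.237) and 7 at 48 h (0.187). The 1 gene lower at 2 h was called lower at none of these times. Of 734 genes called at any time, 35 were higher and 2 lower at 4, 24 and 48 h. Across all tested genes, which are not independent replicates, the log2 changes of 24 and 48 h had r = 0.62 and those of 2 and 24 h r = −0.09. The second flow cell held ABA libraries at 24 and 48 h but a control library at 2 h, and its differences correlated across these groups (r = 0.36 to 0.47). A shift of that flow cell could raise the first r and the shared calls of 24 and 48 h, and lower the second r. These values were not computed without it. The test of a differing effect between times called 31 genes (edgeR), with the strongest change at 4 h in 4, at 24 h in 22 and at 48 h in 5. This count was 15 without the second flow cell, 149 without the count filter and 344 by DESeq2. It was 4, 10 and 2 when replicate number 2, 3 or 4 was left out of all groups.

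**Figure D2:**
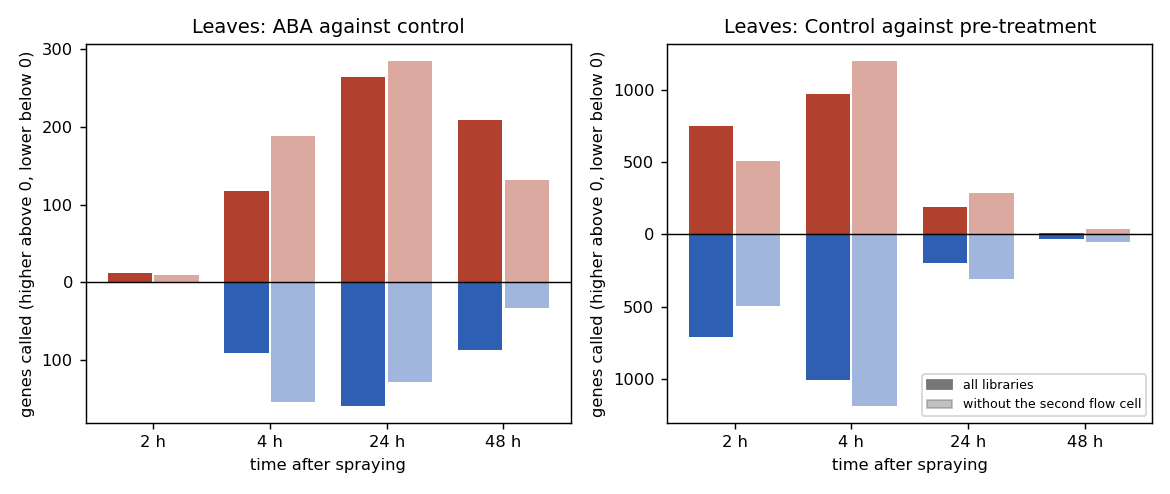
Genes called in leaves by edgeR, higher (red, upward) and lower (blue, downward), for ABA against control and for control against pre-treatment at each time in hours; dark bars use all libraries and pale bars leave out the second flow cell. ABA calls were most numerous at 24 h (422) and control calls at 4 h (1984).

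At 2 and 4 h more genes were called in control leaves against pre-treatment leaves than with ABA against control. Controls were set against 8 pre-treatment libraries and ABA against 4 control libraries, so the comparisons differ in their power to call genes. In control leaves 751 genes rose and 714 fell by 2 h, 973 rose and 1011 fell by 4 h, 194 rose and 199 fell by 24 h, and 9 rose and 28 fell by 48 h (edgeR). The median log2 change of the genes that rose was 0.90 at both 2 and 4 h, and of those that fell −0.79 and −0.89. Without the second flow cell the counts were 1004, 2389, 592 and 94. The 48 h count was 120 by DESeq2, 90 with the flow cell as a term and 12 with only the compared groups in the fit, which gave 936 at 2 h.

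Single libraries moved the control counts too. The 2 h count was 834 without control replicate 1, and the 4 h count 1311 and 1288 without control replicates 2 and 4. The 24 h count was 217, 152 and 125 without control replicates 2, 3 and 4, and 255 without one pre-treatment library. The 48 h count was 2 and 10 without control replicates 2 and 3.

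In buds the ABA and control libraries were compared at each time. Each time had 1 summed library per treatment, so these differences have no replicate check and no p-value. At least 2-fold higher with ABA were 1708 genes at 6 h, 2549 at 12 h, 1749 at 24 h, 2058 at 48 h and 1280 at 72 h. At least 2-fold lower were 874, 2445, 1253, 1830 and 1183. As background, pairs of the 4 single control columns of 48 h, which hold fewer counts than the summed libraries, had 591 to 965 genes at least 2-fold apart (median 722.5). The spread between these columns may be technical, so this background may hold no spread between separate samples. Without the count filter the totals of 2582 at 6 h and 2463 at 72 h were 4103 and 4481. Tests gave 4873, 5773, 7973 and 4315 genes at 6, 24, 48 and 72 h with the spread of the 48 h columns (edgeR), and 1260, 3226 and 1304 at 6, 12 and 72 h by DESeq2. The spread for DESeq2 came from the same 48 h columns, which may be technical. With every column taken as a replicate, 6254 to 9026 genes were called (edgeR). Across the 16214 genes the log2 differences of 6, 12, 24 and 48 h correlated with r from 0.50 to 0.79, and those of 72 h with the others from 0.23 to 0.45.

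Taking the 5 times as blocks, 1580 bud genes rose and 1057 fell with ABA (edgeR, 5 ABA against 5 control libraries), 16.3% of those tested. At least 2-fold higher were 1213 and at least 2-fold lower 611, and 113 genes rose and 1 fell by at least 16-fold. The median log2 change was 1.45 for genes that rose and −1.08 for genes that fell. The total of 2637 was 1583 without 12 h, 1027 without 24 h, 1289 without 48 h and 4133 without 72 h. Genes called higher from the 4 other times had a median log2 difference at the time left out of 1.29 at 6 h, 2.44 at 12 h, 2.18 at 24 h, 2.23 at 48 h and 0.28 at 72 h. For genes called lower these medians were −0.60, −1.07, −1.25, −1.54 and −0.21.

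The bud gene with the largest rise by the naming rule, Vitvi18g01567, had 465 counts in the 5 ABA libraries and 2 in the 5 controls, a ratio of 275 with a 95% counting interval of 75.8 to 2281. Its ABA levels ran from 3.70 to 26.4 CPM, all above every control (edgeR adjusted p = 0.000122). The bud gene furthest below its controls by the naming rule (at least 5 CPM on average, no overlap between ABA and control libraries), Vitvi10g01636, had a log2 change of −3.49 ± 0.39 (SE, edgeR adjusted p = 0.00077). It stood at 123 ± 124 CPM with ABA and 1428 ± 1293 CPM in controls (SD over 5 times), lower at all 5 times. The pre-treatment library stood at 138 CPM, the ABA libraries at 52.1 to 101 CPM from 6 to 48 h and at 343 CPM at 72 h, and the controls at 423 to 3526 CPM. The most abundant gene of the 12 h ABA library held 7.71% of its counts, against 0.795% in the 12 h control and 0.617% in the 72 h ABA library.

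**Figure D3:**
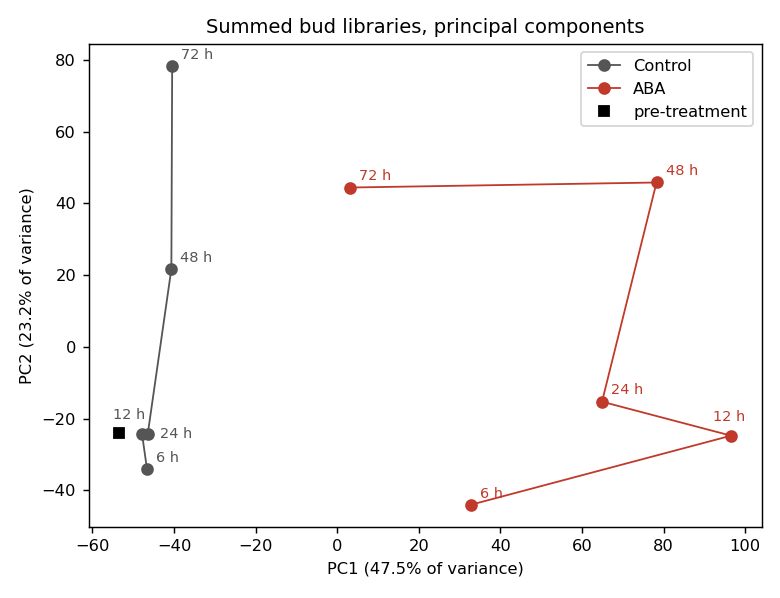
Summed bud libraries on the first principal components, PC1 (47.5% of the variance) and PC2 (23.2%), in log2 CPM units and labelled by hours after spraying; lines join ABA (red) and control (grey) times. The ABA libraries lie apart from controls on PC1, with the 72 h ABA library nearest to them.

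Control buds differed most from pre-treatment at 72 h, without a steady course before. At least 2-fold apart from the pre-treatment library were 1318 genes at 6 h, 1013 at 12 h, 1714 at 24 h, 2221 at 48 h and 4629 at 72 h, without a replicate check and against the same background of 591 to 965, which may be technical only. Without the count filter the first 4 were 2330, 2151, 2808 and 3379, and with a prior count of 5 the 12 h count was 667. Tests gave 2762, 1899, 3420, 5857 and 7903 with the spread of the 48 h columns (edgeR) and 520, 386 and 706 from 6 to 24 h by DESeq2, and with every column taken as a replicate 4223 to 9256 (edgeR). The spread for DESeq2 came from the same 48 h columns. A linear trend over the 6 control libraries rose in 2419 genes and fell in 1797 (edgeR). Without the 72 h library its total of 4216 was 599.

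Lists made from control buds at other times were followed under ABA, with 10000 random lists matched on expression as background. Genes of a list may respond together, and each difference sets a single library against a single library. The percentiles therefore measure only the drawing of genes. The 1194 genes at least 2-fold higher in controls at both 48 and 72 h had median ABA differences of 0.16 at 6 h, 0.31 at 12 h and 0.02 at 24 h (percentiles 100, 100 and 81.2). The 614 genes at least 2-fold lower there had medians of −0.23, −0.77 and −0.26, below all random lists. The 164 genes higher in controls at 6 and 12 h had medians of 0.11 at 24 h, −0.29 at 48 h and −0.29 at 72 h (percentiles 92.1, 0 and 0). The 196 genes lower there had medians of 0.34, 0.52 and 0.16 (percentiles 100, 100 and 95.9). Several of these medians moved. Without the count filter the late higher list had 0.072, 0.18 and −0.033, the late lower list −0.11 at 6 h and −0.044 at 24 h, the early higher list 0.00 at 24 h and the early lower list 0.029 at 24 h and 0.21 at 48 h. Without column number 1, 2 or 3, the 24 h medians were 0.22, 0.15 and 0.14 (early lower), 0.044, 0.040 and 0.043 (early higher) and −0.014, −0.025 and 0.087 (late higher). Without number 2 the early higher list also had −0.11 at 48 h and −0.19 at 72 h, and the early lower list 0.26 at 72 h. With RLE size factors the late higher list had 0.10 at 6 h and 0.0094 at 24 h, and the early higher list 0.047 at 24 h. With lists of genes at least 4-fold apart, of 189, 43, 2 and 8 genes, several signs turned. The late lists then had medians of −0.19 (higher in controls) and 0.44 (lower) at 6 h and of −0.39 (higher) and 1.13 (lower) at 24 h, with −0.18 (lower) at 12 h. The early higher list had 0.84, 1.84 and 0.89 at 24, 48 and 72 h, and the early lower list 2.12 at 24 h and 0.72 at 72 h.

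Whether the ABA effect differed between bud times could be tested only with the spread between the 4 control columns of 48 h, a biological coefficient of variation of 0.0659 on 3 residual degrees of freedom. That test called 8671 genes (edgeR). The spread between those columns may be technical, so this count compares the libraries and not the times as conditions.

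Genes that rose with ABA in leaves were also higher with ABA in buds from 6 to 48 h. The 252 genes that rose in leaves at 24 h and were tested in buds had median log2 differences in buds of 0.77, 1.72, 1.25 and 1.48 at 6, 12, 24 and 48 h, above all 10000 random lists, and 0.03 at 72 h (percentile 79.4). The 116 genes of leaf 4 h had 0.94, 2.16, 1.67 and 1.50, then 0.11 at 72 h (percentile 97.0), and the 198 genes of leaf 48 h had 1.11, 2.26, 1.78 and 1.88, then 0.30 (percentile 100). Genes that fell in leaves had medians nearer 0 in buds from 6 to 48 h than those that rose. The 152 genes of leaf 24 h had −0.37, −0.71, −0.48 and −0.61, then 0.04 at 72 h, and their 24 h value was −0.29 without the count filter and −0.19 when replicate number 2 was left out of leaf groups and bud columns together. The 80 genes of leaf 48 h had −0.36, −0.51, −0.36 and −0.45, then −0.14. The 48 h value of the latter was 0.16 without number 2 and −0.94 without number 4, in leaves and buds together. The 73 genes of leaf 4 h had −0.34, −0.32, −0.41 and −0.32, and −0.68 at 72 h. Setting bud genes without counts at their bound moved no median by more than 0.0114. Percentiles here measure only the drawing of genes, since genes of a list may respond together and each bud time had a single library per treatment.

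**Figure D4:**
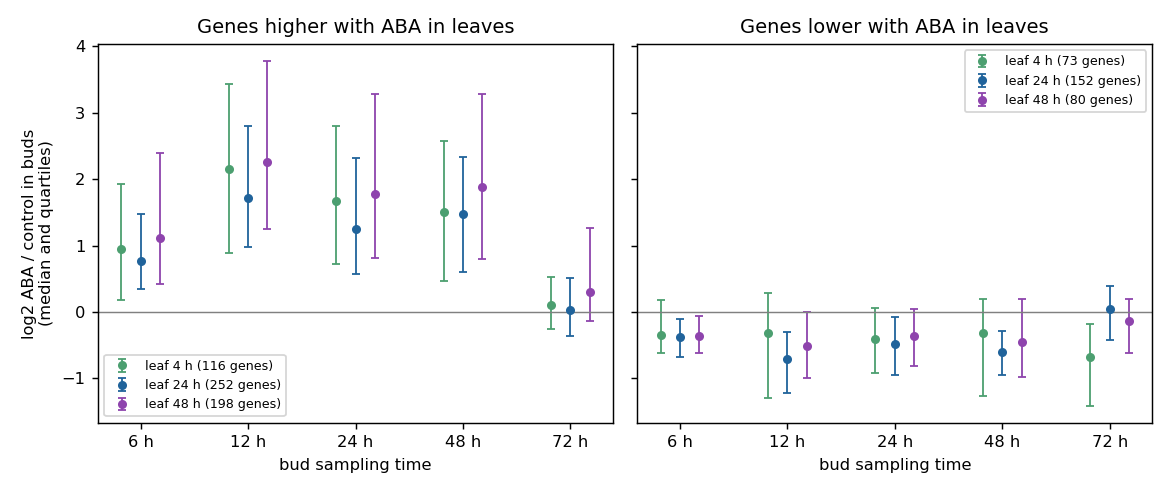
Median and quartiles of the log2 ABA to control ratio in buds at each time (hours) for genes that rose (left) or fell (right) with ABA in leaves at 4, 24 or 48 h. Medians of the higher lists lie between 0.77 and 2.26 from 6 to 48 h and between 0.03 and 0.30 at 72 h.

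Of the genes that rose in leaves, 66 of 116 at 4 h, 140 of 252 at 24 h and 131 of 198 at 48 h also rose in the bud test with time as a block, against 11.4, 24.8 and 19.5 for independent lists. Of those that fell, 23 of 73, 27 of 152 and 15 of 80 also fell in buds, against 4.73, 9.86 and 5.19. At the matched times, with the 2-fold lists of buds, 148 higher (25.8) and 32 lower genes (10.1) were shared at 24 h, and 138 (24.9) and 19 (7.02) at 48 h. The totals of 180 and 157 moved to between 54 and 143 and between 33 and 204 when one replicate number was left out of the leaf groups and the bud columns together. It was 112 without number 1, 66 without 2 and 54 without 4 at 24 h, and 41, 33 and 46 without 2, 3 and 4 at 48 h. Across the 12537 genes tested in both, which are not independent replicates, r was 0.31 at 24 h and 0.38 at 48 h. It was 0.39 at both times without the second flow cell, 0.129 and 0.200 without the count filter, and 0.196 at 24 h without replicate number 2 in leaves and buds.

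**Figure D5:**
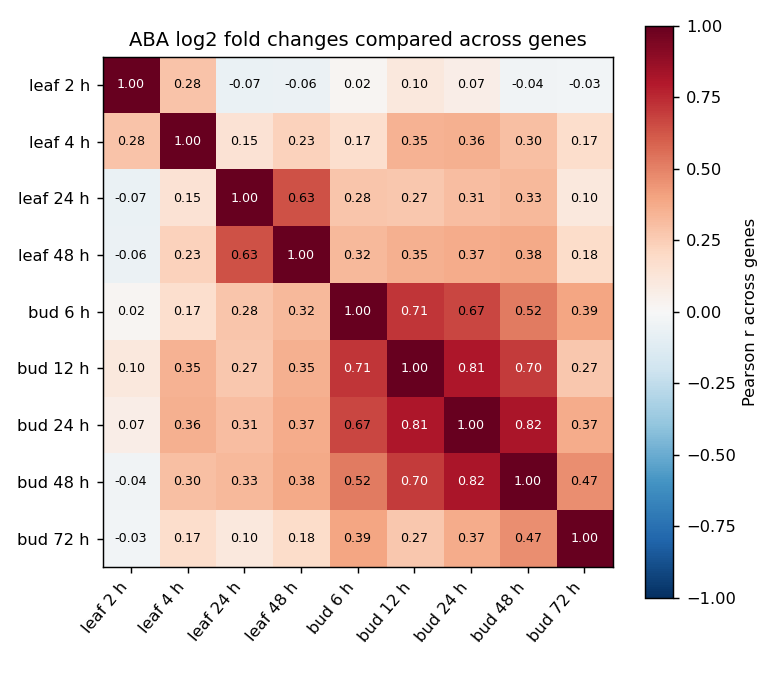
Pearson correlation across 12537 genes of the log2 ABA effects of each pair of times (leaf 2 to 48 h, bud 6 to 72 h), coloured from −1 to 1. Bud times from 6 to 48 h correlate at 0.52 to 0.82, and leaf 24 and 48 h correlate with bud 6 to 48 h at 0.27 to 0.38.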

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

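The tests of repeat runs, of separate samples, of a shift between flow cells, of time of day, of the second flow cell in controls and of the spray, and the reading of the other pairs of ABA libraries left out, were chosen after the result was seen. Whether other splits of the same samples give as many genes was planned.

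Bud columns of a group differed by about sampling noise in 10 of 11 groups. The column numbered 2 was the deepest in all 10 of those groups, with 1.10 to 1.15 times the counts of column 1, as repeat sequencing runs of one library would be if a run's depth is shared. The 48 h control columns had a coefficient of variation of 0.0646 against 0.0134 to 0.0227 elsewhere, but it is not known whether they are separate samples, so separate samples with little spread stay open. No biological explanation was tested.

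Without the second flow cell the 48 h ABA calls in leaves fell from 296 to 164, of which 113 were shared. The 183 genes lost had a median absolute log2 change of 0.973 before and 0.796 after, 100% of those tested again had the same sign and 9.34% had under 0.5 of their earlier change. Both estimates share the controls and the first flow cell's ABA libraries, and the genes were chosen with all libraries in. Part of this likeness is thus built in, and it argues only weakly against a shift of those libraries as the whole source of the lost calls. Differences between the flow cells still correlated across groups (r = 0.41 for ABA 24 and 48 h, 0.47 for control 2 h and ABA 48 h, 0.36 for control 2 h and ABA 24 h) and 36 genes differed between them within ABA 48 h, so the part of such a shift stays open. Leaving out the 2 ABA libraries of the first flow cell gave 1286 calls, but the ABA libraries then all lay on the second flow cell and the controls on the first, so a shift could raise that count and it says nothing on fewer libraries. Leaving out ABA replicates 2 and 3 gave 26 calls, 2 and 4 gave 52, 3 and 4 gave 134, 1 and 3 gave 251 and 1 and 4 gave 375, so these pairs cannot tell whether fewer libraries account for the loss, and no biological explanation was tested.

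Control leaves differed from pre-treatment at 2 and 4 h, with 1465 and 1984 genes called, and less at 24 h (393) and 48 h (37). Of the genes called at 4 h, 80.5% had the same sign in ABA leaves of 4 h against 24 h (all tested genes 59.5%) and 89.0% against 48 h (61.8%), and of those called at 2 h 62.8% (49.3%) and 79.9% (54.8%), so time of day stays open for leaves sprayed at noon, less clearly at 2 h, and the hour of the pre-treatment sampling is not given. No pre-treatment or 4 h control library was on the second flow cell, and at 2 h it is argued against as the whole source by 1004 calls without it and 834 without its 1 control library alone. A passing response to the spray predicts the same course, and the 393 calls at 24 h cannot tell it from time of day.

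For the leaf ABA comparisons with only the compared groups, the real split gave 12, 234, 262 and 56 genes at 2, 4, 24 and 48 h, and the highest of the 34 other splits 1, 5, 6 and 1. So 1 of 35 splits was as large each time, the smallest share these splits can give. This argues against chance at each time taken alone, without adjustment for the number of times. At 48 h the 2 libraries of the second flow cell lay in the ABA group, so the real split also followed the flow cell. At 2 h (control) and 24 h (ABA) 1 library was on the second flow cell, and it lies wholly on one side in every split. For controls against pre-treatment the real counts were 936, 1771, 328 and 12 and the highest other of 100 drawn splits 4, 399, 78 and 19, with 1, 1, 1 and 2 splits as large. The share was under 0.05 at 2, 4 and 24 h, which argues against chance there. At 48 h the share was under 0.05 too, but another split gave more genes than the real one and the count fell to 2 without control replicate 2. For the test of a differing ABA effect in leaves, 3 of 100 splits gave 31 genes or more and the highest other gave 190. These splits drew the labels anew at each time separately, so an ABA effect alike at all times can appear in them as a differing one. They therefore cannot tell whether 31 genes exceed what an unchanging effect would give. For the bud test with time as a block the real count was 2637 and the highest other of 16 swaps 0, and 16 swaps are too few for a share under 0.05.

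Single samples stood apart from their group in 8 of 44 checks over groups of 4 to 10 samples. Chance gives about 1 in 20, but 3 of the 8 are groups in which a gene had 1 to 3 counts in one library and none in the others, which the check always marks, so the number is not set against that rate. A total of 1321798 counts in control 2 h lay below the next, 2238365. Detected genes numbered 18269 in one control 4 h library (next 17815). The most abundant gene held 2.92% of one ABA 48 h library (next 2.23%) and 2.81% of one ABA 4 h library (next 2.35%). Vitvi05g00204 stood at 0.508 CPM in one pre-treatment library, 1.25 in one ABA 4 h library and 0.474 in one control 24 h library, where the next were at 0, and at 232 in one ABA 48 h library (next 21.0). The test of an ABA effect differing between times called 31 genes in leaves, where other splits gave up to 190 and leaving out replicate number 4 gave 2. In buds it called 8671 with the spread of 4 columns, which sets single libraries against each other and does not test the times as conditions.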

How the results depend on the processing

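The bud alternatives with the spread of the 48 h control columns, with other prior counts, with a time left out and with 4-fold lists were chosen after the data were seen. Every bud column a replicate was the planned test, given here as an alternative because the columns were summed. So were all alternatives of the bud test with time as a block and of the control trend. The same holds for all alternatives of the medians of leaf lists in buds and of the bud lists in leaves. Over all alternatives 355 values stayed within the limits set for them, 144 moved, 6 reversed and 3 lost their call. For counts of genes the limit was a fixed ratio to the main count, and for tests it was whether the call held. For r and the medians of leaf lists it was the spread over the left-out replicates, which are among the values judged. For control lists it was an error from the drawing of genes only. These tallies therefore do not measure stability. Where a value moved, the cause was not tested, apart from the checks described above on the 48 h leaf calls without the second flow cell. The named genes had adjusted p (edgeR or DESeq2) from 9.69e-06 to 0.0351 (Vitvi05g00204), 1.04e-05 to 0.00322 (Vitvi08g00768), 1.64e-15 to 0.00175 (Vitvi18g01567) and 2.86e-25 to 0.00792 (Vitvi10g01636) over their 45 alternatives, and kept their direction; Vitvi05g00204 was not among the genes tested with only the compared groups. Not run were the gene list tests (no gene names), bud fits of only the compared groups (no residual degrees of freedom), a replicate block for bud list medians and the bud side of overlaps, and DESeq2 or left-out replicates for the bud test of differing effects. The control lists were planned from genes called by the edgeR test, and the reported 2-fold definition was chosen after the bud columns had been compared. With the counts thinned to 0.5 (5 draws, run after the data were seen), ABA calls in leaves were 4 to 16, 125 to 165, 281 to 310 and 191 to 210 at 2, 4, 24 and 48 h, and the time-block calls in buds 2113 to 2188, so depth limits the counts except at 2 h, where the draws lay on both sides of 13.

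Leaf replicate numbers did not pair the samples. Same-numbered libraries correlated at −0.219 to 0.162 over 16 pairs, 2 of them over 0.1, and 3 correlated best with their own number. With the replicate block the ABA counts in leaves were 12, 203, 398 and 288, the control counts 1379, 1957, 427 and 39, and the differing effects 23. The block on bud columns, every column a replicate, gave 6947, 8684, 7676, 8820 and 6270 ABA genes at 6, 12, 24, 48 and 72 h and 5183, 4354, 5716, 6901 and 9290 control genes. With the replicate block in the leaf fit, 168 and 154 genes were shared with buds at 24 and 48 h.

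In leaves, without the count filter ABA at 2 h gave 27 genes and the differing effects 149. With the flow cell as a term ABA at 4 h gave 343, with all 208 of the main count among them, and controls at 48 h 90. No library of these comparisons was on the second flow cell, so the term could act there only through the spread estimated over all leaf groups. Without the second flow cell ABA gave 342 at 4 h and 164 at 48 h, controls 592 at 24 h and 94 at 48 h, and the differing effects 15. DESeq2 gave 33 and 338 ABA genes at 2 and 4 h, 120 control genes at 48 h and 344 differing effects. With only the compared groups ABA gave 262 at 24 h and 56 at 48 h, and controls 936 at 2 h and 12 at 48 h. Leaving out one replicate gave 4 to 20, 68 to 174, 234 to 383 and 123 to 640 ABA genes at 2, 4, 24 and 48 h, 834 to 1537, 1288 to 1984, 125 to 487 and 2 to 50 control genes, and 2 to 30 differing effects.

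In buds, without the count filter ABA gave 4103 genes at 6 h and 4481 at 72 h, and controls 2330, 2151, 2808 and 3379 at 6, 12, 24 and 48 h. A prior count of 5 gave 667 control genes at 12 h. With the spread of the 48 h columns edgeR called 4873, 5773, 7973 and 4315 ABA genes at 6, 24, 48 and 72 h and 2762, 1899, 3420, 5857 and 7903 control genes at 6 to 72 h. DESeq2 called 1260, 3226 and 1304 ABA genes at 6, 12 and 72 h and 520, 386 and 706 control genes at 6, 12 and 24 h. The spread for DESeq2 came from the same 48 h columns. With every column a replicate ABA called 6880, 8572, 7610, 9026 and 6254 and controls 5081, 4223, 5628, 7196 and 9256. The time-block count was 1027 to 4133 with one time left out (1583 without 12 h, 1027 without 24 h, 1289 without 48 h, 4133 without 72 h), and the control trend 599 to 4061 (599 without 72 h).

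Between leaves and buds, r at 24 h was 0.129 without the count filter and 0.395 without the second flow cell, and at 48 h 0.200 without the count filter. With one replicate number left out of leaves and buds together r was 0.196 to 0.386 at 24 h and 0.265 to 0.369 at 48 h, and the shared genes 54 to 143 and 33 to 204. Medians of the higher leaf lists in buds were then 1.31 to 1.75 at 24 h and 1.44 to 2.67 at 48 h, and of the lower lists −0.60 to −0.19 and −0.94 to 0.16, the last reversed without number 2 in both. Without the count filter the 24 h medians were 1.52 and −0.29. The lists lower in buds lost their call in leaves with an estimated correlation, at adjusted p (camera) of 0.0919, 0.0980 and 0.0919 at 4, 24 and 48 h. By fry they kept it, at adjusted p of 0.0190, 0.0234 and 0.0234.

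For the control lists in buds, other size factors gave 0.10 (late higher) and −0.30 (late lower) at 6 h. Without the count filter the early higher list had 0.00 at 24 h, the early lower list 0.029 and 0.21 at 24 and 48 h, the late higher list 0.072, 0.18 and −0.033 and the late lower list −0.11, −0.59 and −0.044 at 6, 12 and 24 h. With lists at least 4-fold apart the early higher list had 0.84, 1.84 and 0.89 and the early lower list 2.12, 0.78 and 0.72 at 24, 48 and 72 h, the late higher list −0.19 at 6 h and −0.39 at 24 h, and the late lower list 0.44, −0.18 and 1.13 at 6, 12 and 24 h; of these the early higher list at 48 and 72 h, the late higher at 6 h and the late lower at 6 and 24 h reversed. With one column number left out the early higher list had −0.35 to −0.11 at 48 h, the early lower 0.14 to 0.22, 0.40 to 0.49 and 0.12 to 0.26 at 24, 48 and 72 h, the late higher 0.16 to 0.24, 0.28 to 0.38 and −0.025 to 0.087 and the late lower −0.28 to −0.26 at 6 h and −0.37 to −0.20 at 24 h.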

Other observations

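The tests of a shared ABA response, of neighbouring genes and of a slower course had their predictions written before the result was seen; the slower course at times other than 72 h was read after.

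A group of 35 leaf genes rose with ABA at 4, 24 and 48 h, with median log2 changes of 1.86, 2.07 and 1.75 (quartiles 1.39 to 2.34, 1.54 to 2.53 and 1.39 to 2.45), and stood at 0.71 at 2 h. All 35 were tested in buds, where 28 rose with time as a block, against 3.44 for independent lists. Their median log2 difference in buds was 1.86 at 6 h, 3.15 at 12 h, 2.48 at 24 h, 2.29 at 48 h and 0.10 at 72 h.

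The genes that rose with ABA in buds were followed in leaves. The 1233 of them tested in both had median log2 changes in leaves of −0.07 at 2 h, 0.27 at 4 h, 0.33 at 24 h and 0.37 at 48 h. By camera they ranked higher at 4 h (adjusted p = 2.53e-11), 24 h (5.72e-13) and 48 h (8.60e-18) and not at 2 h (0.756), and with an estimated correlation the adjusted p was 0.0358, 0.0312 and 0.0159 at 4, 24 and 48 h. The 813 genes that fell in buds had medians of 0.00, −0.18, −0.15 and −0.16, with adjusted p (camera) of 3.15e-07, 2.23e-06 and 5.01e-07 from 4 h and of 0.0919, 0.0980 and 0.0919 with an estimated correlation. By fry the adjusted p at 4, 24 and 48 h was 0.00827, 0.00258 and 0.00156 for the higher list and 0.0190, 0.0234 and 0.0234 for the lower list. A shared ABA response of both tissues is consistent with the higher list, as a hypothesis.

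Genes called by ABA in buds may lie beside each other, if consecutive identifier numbers mark neighbouring genes, which the tables do not state. Among 8654 pairs of consecutive numbers tested, 185 were called in one direction, against a median of 120 and a highest of 151 in 1000 shuffles. Reads shared between copies of a gene were not excluded.

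A slower course of the buds under ABA is a hypothesis from the controls' time course. The 72 h ABA library lay nearer to the 48 h control (root mean square log2 difference 0.685) than to the 72 h control (0.778), as a slower course would give. The ABA libraries of 6, 12 and 24 h went the other way, nearest to the later controls of 24 h (0.774, own time 0.805), 48 h (1.18, own time 1.22) and 48 h (0.946, own time 0.955), and that of 48 h was nearest to its own time (1.11). Over the 13387 genes not called in the bud test with time as a block, the 24 h ABA library was nearest to its own time (0.611, 48 h control 0.618). That of 12 h was then nearest to the 24 h control (0.786, 48 h control 0.788), and those of 6, 48 and 72 h kept their nearest control. Each ABA and control time is a single library without a spread, so these values cannot tell whether ABA slowed the course.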
